A study of Homo sapiens with 6 samples.

How the data were processed

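Gene expression of SKOV3, an established human epithelial ovarian cancer cell line, was measured on 6 Agilent 1-colour (Cy3) microarrays, 3 from cells cultured alone and 3 from cells co-cultured with myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cell responses. Per the labels' protocols, 250000 SKOV3 cells shared a transwell system, in which a porous membrane parts the cell populations, with 500000 freshly sorted MDSCs from ovarian cancer or with medium for 24 h. Total RNA was then purified on columns, amplified and labelled with Cy3. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures or separate MDSC preparations, so p-values measure the spread between these samples, which may be technical.

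Per the file headers, the arrays were read with Agilent Feature Extraction 12.0.3.1 under protocol GE1_1200_Jun14, the array design was 072363 and probe coordinates were on hg19. The deposited scanner output held 1 row per spot with the processed green signal as an intensity on a linear scale, background-subtracted and detrended within the array by Feature Extraction and not normalized between arrays, with a surrogate value in place of signals that did not exceed background. It also held the mean spot intensity and the median local background intensity, per the file headers. The other deposited columns, flags of value 0 or 1 for spots well above background, saturated, non-uniform or outlying, were used as filters. The submitters' processing notes name limma without a role or version, and the normalization the authors used is not given in the sources used here.

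The deposited value table of the series held values on the log2 scale, and its scale was found by setting each column against that array's scanner output. Column medians were 3.25, 3.25 and 3.24 for controls 1 to 3, and 4.96, 5.11 and 5.01 for co-cultures 1 to 3. The 3 control columns followed the log2 processed signal of their arrays, with Pearson r across probes from 0.99993 to 0.99997 and at least 99.9% of 58341 rows within 0.3 log2 units. The 3 co-culture columns did not, with r from 0.335 to 0.342 and at most 15.9% of rows within 0.3. The table was therefore used only as an alternative, on rows that followed the scanner output, and all results come from the scanner output. Its centring and the method behind it stay unknown.

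Each array held 62976 spots, of which 60901 were not controls and represented 58201 probes. Between 50.8% and 53.6% of spots per array were well above background, the 75th percentile of the processed signal lay between 195 and 211 units, and at most 1 spot per array was saturated. The number of arrays, 3 a group, limits the precision. All 6 arrays lay on 1 slide and were read in 1 scan, so a slide block was not run.

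Spots of one probe were averaged on the log2 scale, and each array's 75th percentile of log2 processed signal was subtracted. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 28602 probes. Probes were named through the RefSeq table of assembly GRCh38.p14, used for names only: 31104 probes matched by accession, 3366 by current symbol and 496 by a synonym, and 23235 had no current symbol. A gene was represented by its kept probe with the highest mean level over all 6 arrays, which gave 15988 genes. A list member is called measured where it is among these genes. A member not measured was too dim to be kept or had no named probe. Of the called genes, 312 had 2 or more kept probes, and for 2 of them another kept probe was called in the opposite direction. Near-identical genes such as SAA1 and SAA2, CXCL1, CXCL2 and CXCL3, AKR1B10 and AKR1B15 or the metallothionein genes can share hybridization signal, so their separate values are uncertain.

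Co-culture was compared with control using limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. Errors of log2 fold changes are standard errors of that fit with n = 3 arrays a group. Exact permutation of 3 against 3 arrays cannot give a two-sided p under 0.1, so single genes were tested through limma only. A probe not well above background on any array of a group has only a bound there. For such genes "at least N-fold" compares the bright group's mean with the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such bounds hold for this processed signal only, and another background correction can give far smaller fold changes.

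The 34 gene lists, 29 of pathways and 5 of markers of other cell types, were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The tests, thresholds, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule named CSF2 and STAT3 from the series title, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and which carry a current symbol (loci without a proper gene name left out), and up to 4 members with the smallest adjusted p in each list. TNFAIP3, NFKBIA, SOCS3, IFIT1 and ALDH1A1 fall outside that rule and were chosen after their values were seen. Symbols in the lists were updated where the RefSeq table gave a newer one, which changed 1 symbol, DDX58 to RIGI.

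The pipeline was tested on simulated data with 200 of 15988 genes changed. It recovered 11 of 50 genes at a log2 fold change of 0.5, 28 of 50 at 1, 46 of 50 at 2 and 49 of 50 at 4, with 1 false call among 135. The simulated noise was normal and independent between probes, without the shared deviations of real arrays. The share of false calls therefore does not carry over to the real calls.

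The titles give both groups the same replicate numbers. Deviations from the group means correlated across probes within every same-numbered pair (r = 0.221, 0.192 and 0.250 for numbers 1, 2 and 3), while the 6 other combinations gave r from -0.158 to -0.0723. Deviations cancel out within a group, so positive values in same-numbered pairs bring negative ones elsewhere, which are not separate evidence. Same-numbered arrays also lay side by side on the slide, so the correlation cannot tell shared samples from a shared position. From the titles and this correlation the numbers may pair the samples, but the source of any pairing is not given in the sources used here. The planned fit has no block, so the main results ignore any pairing. A fit with the replicate number as a block was run as an alternative.

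Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter on dim probes, only probes well above background on all 6 arrays, outlying spots left out, the mean over a gene's probes, eBayes with trend and robust options, array weights, the replicate block, leaving out each array in turn, and the value table. The estimated correlation as an alternative for list calls and the list counts without each array were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading the files and drawing the plots. Results of 3 genes are not reported here.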

Results

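The data comprised 6 whole-transcriptome arrays of SKOV3 ovarian cancer cells after 24 h, 3 from cells cultured alone (control) and 3 from cells that shared a transwell system with MDSCs (co-culture). The arrays correlated with one another at r between 0.982 and 0.995 across probes. The first principal component held 50.7% of the variance and separated the groups, and the second, with 20.4%, set control 2 and co-culture 2 apart from the other 4 arrays. The single comparison the design implies asks which genes of the tumour cells differ when MDSCs are present. The series title names CSF2, phosphorylated STAT3 and stemness as its subject. These arrays measure transcript levels, so they report neither phosphorylation nor stemness as a property of the cells.

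Transcript levels of several secreted inflammatory mediators, among them CSF2, IL6 and CXCL8, were far higher in co-culture than in control. The RNA was taken as that of SKOV3 cells, and a contribution of RNA from the MDSCs stays open. CSF2, which encodes the myeloid growth factor GM-CSF, was not well above background on any control array and was at least 47.0-fold higher in co-culture (limma adjusted p = 0.00459, higher in 3 of 3 co-culture arrays than in every control array). IL6, encoding an inflammatory cytokine that signals through STAT3, rose 58.3-fold (log2 fold change 5.86 ± 0.33, limma adjusted p = 0.00229), and the neutrophil chemoattractant CXCL8 rose 30.2-fold (4.92 ± 0.34, limma adjusted p = 0.0035). With normexp background correction their log2 fold changes were smaller, 5.24 for IL6 and 3.69 for CXCL8. STAT3 itself rose by less, 1.49-fold (0.58 ± 0.09, limma adjusted p = 0.0163). Falls were smaller in size, led among genes measured in both groups by VAV3, a guanine nucleotide exchange factor, which was 6.98-fold lower (log2 fold change -2.80 ± 0.36, limma adjusted p = 0.0126). With normexp VAV3 had a log2 fold change of -2.21.

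The CSF2 probe lies on chromosome 5 from 131411452 to 131411511 (hg19). Its fitted log2 fold change of 7.14 ± 0.58 rests on control signals not well above background and is not a measured ratio. With normexp background correction the fitted value was 2.69, so the bound given for CSF2 holds for the signals without that correction. The gene passed the limma threshold under each alternative that gave it a value. The IL6 probe lies on chromosome 7 from 22771207 to 22771266 and the STAT3 probe on chromosome 17 from 40474404 to 40474463. STAT3 did not pass without control 1, control 2, control 3 or co-culture 1, with limma adjusted p up to 0.0899 over all alternatives and log2 fold changes from 0.52 to 0.61.

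**Figure D1:**
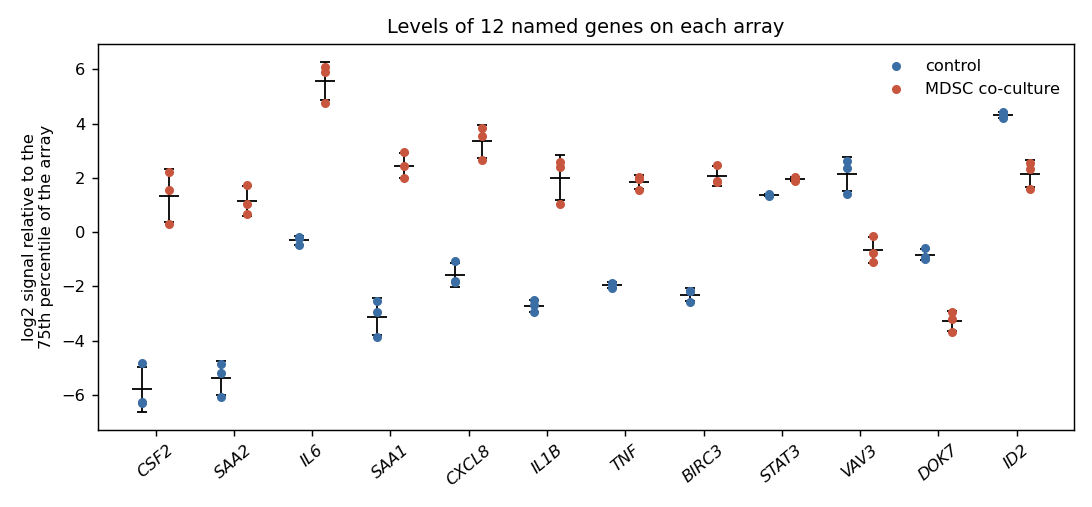
Log2 signal relative to each array's 75th percentile (vertical axis) for 12 named genes on the 3 control arrays (blue) and the 3 co-culture arrays (red), with the mean and SD in black. The control points of CSF2 and SAA2 are not well above background, and the 3 co-culture points of each gene lie on one side of its 3 control points. For all but STAT3 and TNF the rule that chose the largest rises and falls required this.

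In total, 1138 of 15988 genes changed, 584 upward and 554 downward (limma, adjusted p under the threshold), and 345 changed at least 2-fold, 198 upward and 147 downward. By probes, 935 rose and 906 fell. Of 91 called genes named by the rule, 58 did not pass without the filter on dim probes, 11 with normexp and 7 with median scaling. With normexp, whose offset of 50 compresses differences near background, 32 of the 91 had a log2 fold change smaller by more than 1.5 times and 0 had the opposite sign. An unadjusted p under 0.05 was reached by 4208 genes, and the groups did not overlap for 35.6% of genes, where chance gives 10%. With normexp background correction the share of rises was 61.0% in place of 51.3% over all calls and 84.6% in place of 57.4% among calls of at least 2-fold, whose number was 117. Calls numbered 218 without control 1, 242 without control 2, 380 without control 3, 374 without co-culture 1, 457 without co-culture 3 and 943 without co-culture 2. Calls of at least 2-fold numbered 160 without control 1, 175 without control 2 and 224 without co-culture 1.

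The other genes with the largest rises were SAA2, SAA1, CCL20, TNFRSF9, IL1B, IL4I1, BIRC3, CXCL2 and the MIR146A locus. The acute phase gene SAA2, not well above background in controls, was at least 41.0-fold higher (limma adjusted p = 0.00229), and its near-identical neighbour SAA1, well above background on 2 of 3 control arrays, rose 47.5-fold, although the probes may not tell them apart. The T cell and dendritic cell chemoattractant CCL20 was at least 7.78-fold higher, and TNFRSF9, which encodes the costimulatory receptor 4-1BB, at least 14-fold higher (limma adjusted p = 0.00763 and 0.0027). IL1B rose 26.5-fold, IL4I1, which encodes a secreted amino acid oxidase, 25.4-fold, the apoptosis inhibitor BIRC3 20.8-fold and the chemokine gene CXCL2 19-fold (limma adjusted p from 0.00201 to 0.00477). A probe named for the MIR146A locus (chromosome 5, 159914327 to 159914386), which reports its long transcript and not the mature microRNA, was at least 6.08-fold higher (limma adjusted p = 0.0054). Each of these genes passed the limma threshold in every fit that left out 1 array. With normexp the log2 fold changes were 2.37 for SAA2, 3.29 for SAA1, 0.94 for CCL20, 1.21 for TNFRSF9, 0.72 for MIR146A, 2.75 for IL1B and 2.76 for BIRC3, so the bounds given for SAA2, CCL20, TNFRSF9 and MIR146A hold for the signals without that correction.

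NF-kB and TNF target genes rose almost without exception. Of 27 measured members 26 rose and 0 fell, the same numbers as adjusted over the list alone, with a median log2 fold change of 3.30, or 2.96 with the 3 members not well above background in controls set at their bound. The list was called by camera (adjusted p = 1.2e-28), and not with an estimated correlation (camera adjusted p = 0.2 with an estimated correlation). TNF, the cytokine that activates this pathway, rose by 3.80 ± 0.14 on the log2 scale. The NF-kB subunit gene RELB rose by 2.39 ± 0.13, and the feedback inhibitors TNFAIP3 and NFKBIA by 3.85 ± 0.22 and 1.90 ± 0.12 (limma adjusted p from 0.00129 to 0.0027). The count stayed between 21 and 26 in fits that left out 1 array. With normexp TNF had a log2 fold change of 2.38.

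The chemokine, interleukin, acute phase and CSF genes that passed were all higher in co-culture. Among chemokine genes 5 of 11 measured rose and 0 fell (6 up and 2 down adjusted over the list alone). All 5 are shared with the NF-kB list: CXCL1, CXCL2, CXCL3, CXCL8 and CCL20 (camera adjusted p = 0.0016, and adjusted p = 0.2 with an estimated correlation). CXCL1 and CXCL3, close relatives of CXCL2, rose by 3.43 ± 0.26 and 3.30 ± 0.28 on the log2 scale (limma adjusted p = 0.00364 and 0.00477). Interleukin and interleukin receptor genes rose for 10 of 23 measured and fell for 0 (16 up and 0 down adjusted over the list alone). Among them were IL32, which encodes a proinflammatory cytokine, up by 4.21 ± 0.34 and the receptor subunit gene IL1RAP by 1.21 ± 0.12 on the log2 scale (camera adjusted p = 1.33e-08, and adjusted p = 0.16 with an estimated correlation). With normexp CXCL3 had a log2 fold change of 1.82 and IL32 2.87. The interleukin count was 4 without control 1 and 5 without control 2. IL6, IL1A and IL1B, which rose, are also on the NF-kB list. Complement and acute phase genes rose for 11 of 18 measured and fell for 0 (11 up and 1 down adjusted over the list alone). These included C3, the central complement component, up 15.9-fold and the protease inhibitor gene SERPINA1 by 2.74 ± 0.20 on the log2 scale (camera adjusted p = 1.4e-08, and adjusted p = 0.0876 with an estimated correlation). CSF and receptor genes rose for 2 of 7 measured, CSF2 and CSF1, the latter by 0.56 ± 0.09 on the log2 scale, and fell for 0. The numbers were 3 up and 0 down adjusted over the list alone (camera adjusted p = 0.0409, and adjusted p = 0.283 with an estimated correlation). Only 1 CSF gene rose without control 1, control 2, control 3, co-culture 1 or co-culture 3, and 3 rose without co-culture 2. That list was not called by camera with normexp (adjusted p = 0.257), with probes well above background on all 6 arrays (0.207), with the mean over probes (0.0968), or without control 2 (0.0535), control 3 (0.121) or co-culture 1 (0.0977).

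**Figure D2:**
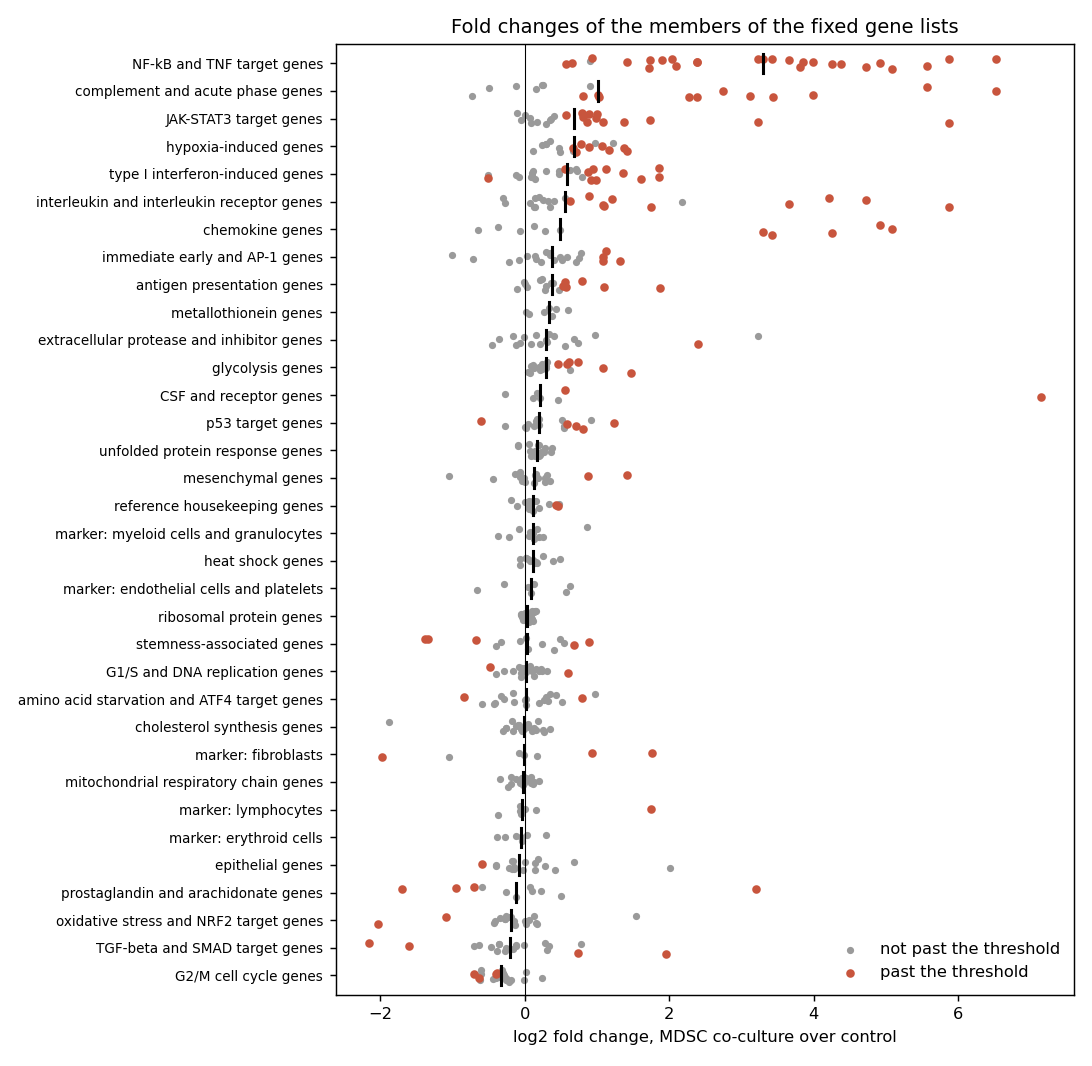
Log2 fold change of co-culture over control (horizontal axis) for each measured member of the 34 fixed gene lists (rows, ordered by median), with members past the limma threshold in red, the others in grey and a black bar at the median. The median of the NF-kB and TNF target genes is 3.30 and that of the G2/M cell cycle genes -0.32; genes not well above background in a group are drawn at their fitted value.

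JAK-STAT3 target genes rose for 12 of 22 measured and fell for 0 (16 up and 0 down adjusted over the list alone), with a median log2 fold change of 0.69 (camera adjusted p = 4.23e-09, and adjusted p = 0.283 with an estimated correlation). The members with the largest rises, IL6, ICAM1 and BCL3, are also on the NF-kB list, so the list is not independent of that one. The feedback inhibitor SOCS3 rose by 0.99 ± 0.19 and the oncostatin M receptor gene OSMR by 0.86 ± 0.10 on the log2 scale, and SBNO2, which encodes a corepressor, 1.99-fold (limma adjusted p = 0.0327, 0.0108 and 0.0114). The adhesion molecule gene ICAM1, not well above background in controls, was at least 3.99-fold higher (limma adjusted p = 0.00563). With normexp ICAM1 had a log2 fold change of 0.41 and did not pass (limma adjusted p = 0.0866). Type I interferon-induced genes rose for 10 of 26 measured and fell for 1, IFIT1, which passed in no fit that left out 1 array (15 up and 1 down adjusted over the list alone). Camera called the list (adjusted p = 3.35e-07, and adjusted p = 0.21 with an estimated correlation). The antiviral enzyme gene OAS3 rose by 1.36 ± 0.09, ISG20 by 1.85 ± 0.22, IRF7 by 0.98 ± 0.12 and IFI27 by 1.60 ± 0.20 on the log2 scale (limma adjusted p from 0.00287 to 0.0117). Antigen presentation genes rose for 6 of 18 measured and fell for 0 (9 up and 0 down adjusted over the list alone). They included the immunoproteasome subunit gene PSMB9 by 1.10 ± 0.11 and the peptide transporter gene TAP1 by 0.57 ± 0.08 on the log2 scale (camera adjusted p = 1.55e-06, and adjusted p = 0.283 with an estimated correlation). Without control 1, control 2, control 3, co-culture 1 and co-culture 3 in turn, the rises numbered 5, 4, 7, 7 and 7 for JAK-STAT3 targets, 3, 4, 5, 5 and 5 for interferon-induced genes, and 1, 2, 3, 3 and 2 for antigen presentation genes.

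Some genes of the hypoxia response and of glycolysis rose, fewer than those that did not pass. Hypoxia-induced genes rose for 8 of 18 measured and fell for 0 (15 up and 0 down adjusted over the list alone). Among them were the mitophagy gene BNIP3, up by 1.07 ± 0.12, the collagen crosslinking enzyme gene LOX by 1.42 ± 0.16 and the collagen hydroxylase gene P4HA2 by 0.71 ± 0.11 on the log2 scale (camera adjusted p = 4.23e-09, and adjusted p = 0.0999 with an estimated correlation). Glycolysis genes rose for 6 of 19 measured and fell for 0 (11 up and 0 down adjusted over the list alone). Among them were the enolase gene ENO2, up by 1.08 ± 0.09 and PFKFB3, a regulator of glycolytic flux, by 0.74 ± 0.10 on the log2 scale (camera adjusted p = 4.24e-07, and adjusted p = 0.0876 with an estimated correlation). Without control 1, control 2, control 3, co-culture 1 and co-culture 3 in turn, the rises numbered 2, 2, 2, 3 and 5 for hypoxia-induced genes and 1, 1, 1, 2 and 1 for glycolysis genes.

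Several further lists were called upward by camera on few members. Immediate early and AP-1 genes rose for 4 of 22 measured and fell for 0, DUSP1, IER3, JUNB and FOS (6 up and 0 down adjusted over the list alone). Camera called that list (adjusted p = 0.00156, and adjusted p = 0.528 with an estimated correlation). The p53 target genes rose for 4 of 19 measured and fell for 1 (5 up and 1 down adjusted over the list alone). The other 14, MDM2 and BAX among them, did not pass. The activity of p53 was not measured, so these rises need not be a p53 response. The growth arrest gene GADD45A rose by 1.23 ± 0.15 and the death receptor genes FAS and TNFRSF10B by 0.71 ± 0.11 and 0.80 ± 0.13. With normexp FAS had a log2 fold change of 0.43. The DNA repair gene DDB2 had a log2 fold change of -0.61 ± 0.13 (camera adjusted p = 0.0059, and adjusted p = 0.283 with an estimated correlation). Without control 1, control 2, co-culture 1 or co-culture 3 the p53 list had 1 rise, and DDB2 kept its call only without co-culture 2. DDB2 did not pass with normexp or median scaling (limma adjusted p = 0.057 and 0.0646), nor FOS with normexp (0.11). The immediate early list had 1 rise without control 1 or control 2 and 2 without control 3, co-culture 1 or co-culture 3. Of 19 extracellular protease and inhibitor genes 1 rose, PLAT, which encodes tissue plasminogen activator, by 2.39 ± 0.22 on the log2 scale, and 2 rose without control 3 or co-culture 2. With the replicate block all 4 members named by the rule rose, PLAT, the matrix metalloprotease gene MMP3, the urokinase gene PLAU and its receptor gene PLAUR (limma adjusted p = 0.0107, 0.0297 and 0.0344 for the last 3). Adjusted over the list alone, 7 were up and 2 down (camera adjusted p = 0.0395, and adjusted p = 0.618 with an estimated correlation). Of 15 reference housekeeping genes 2 rose, PGK1, also a glycolysis gene, and the transferrin receptor gene TFRC (3 up and 0 down adjusted over the list alone). Camera called that list (adjusted p = 0.0321, and adjusted p = 0.407 with an estimated correlation). With the replicate block TFRC did not pass (limma adjusted p = 0.0504), nor with median scaling (0.0686), and housekeeping genes had 1 rise without co-culture 2 and 0 without any other array. Unfolded protein response genes (18 measured, median log2 fold change 0.17) and metallothionein genes (7 measured, median 0.34) were called with 0 members past the limma threshold and 0 adjusted over the list alone (camera adjusted p = 0.0205 and 0.0478, and adjusted p = 0.626 and 0.618 with an estimated correlation). Calls by camera were lost without single arrays for the protease list (adjusted p = 0.0646 without control 2 and 0.19 without co-culture 3) and the housekeeping list (0.0576 without control 1, 0.0646 without co-culture 1 and 0.0542 without co-culture 3). The same held for the unfolded protein list (0.0777 without control 2, 0.0659 without co-culture 1 and 0.079 without co-culture 3) and the metallothionein list (0.126 without control 2 and 0.182 without co-culture 1). With probes well above background on all 6 arrays camera did not call the protease and metallothionein lists (adjusted p = 0.0709 and 0.0602).

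A few genes of mitosis fell in co-culture. The G2/M cell cycle list was the 1 list called downward, with a median log2 fold change of -0.32 over 24 measured members. Of these 4 fell and 0 rose (0 up and 16 down adjusted over the list alone; camera adjusted p = 5.02e-07, and adjusted p = 0.407 with an estimated correlation). The centromere histone gene CENPA had a log2 fold change of -0.63 ± 0.11, the mitotic kinesin gene KIF20A -0.70 ± 0.13, NUSAP1 -0.39 ± 0.09 and the cyclin gene CCNB2 -0.39 ± 0.09 (limma adjusted p from 0.0258 to 0.0483). With the replicate block NUSAP1 and CCNB2 did not pass (limma adjusted p = 0.0566 and 0.0674). With median scaling CENPA, KIF20A, NUSAP1 and CCNB2 did not pass (limma adjusted p = 0.0508, 0.0553, 0.124 and 0.125), nor did they without the filter on dim probes. NUSAP1 and CCNB2 also did not pass with normexp (0.093 and 0.0783), and NUSAP1 with quantile normalization (0.051). In fits that left out 1 array the list had 1 member past the threshold without co-culture 2 and 0 without any other array. G1/S and DNA replication genes were not called (camera adjusted p = 0.775), with 1 of 24 measured up, CCNE1, and 1 down, MCM6, the same numbers as adjusted over the list alone. CCNE1 kept its call only without co-culture 1 or co-culture 2, and MCM6 in no fit that left out 1 array. MCM6 also did not pass with normexp or median scaling (limma adjusted p = 0.114 and 0.0852).

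The largest falls concerned genes of varied function. Among genes measured in both groups, the transcription regulator gene ID2 (an inhibitor of differentiation) was 4.45-fold lower, the adaptor gene DOK7 (well above background on 2 of 3 co-culture arrays) 5.41-fold lower and the long noncoding RNA GACAT2 5.99-fold lower (limma adjusted p = 0.00864, 0.00477 and 0.0108). The others were not well above background in co-culture. The calcium channel gene CACNA1H was at least 5.25-fold lower, the sulfotransferase gene CHST9 at least 3.64-fold lower, the scaffold kinase gene KSR2 at least 3.48-fold lower and the methyltransferase gene TMT1A at least 3.27-fold lower (limma adjusted p from 0.00368 to 0.0229). CBLN2, MNX1-AS1, HLF and SLC47A2 were at least 2.83-fold, 2.26-fold, 2.20-fold and 1.88-fold lower (limma adjusted p = 0.0229, 0.0105, 0.0118 and 0.00695). The antisense RNA MNX1-AS1 is named from the array's annotation, and the probe's strand was not tested against the opposite gene. In fits that left out 1 array, VAV3, KSR2 and CBLN2 lost their call without control 1 or control 2, and HLF and MNX1-AS1 without control 1. The call was lost for KSR2 also without control 3 or co-culture 1, and for CBLN2 also without co-culture 1 or co-culture 3. Limma adjusted p reached up to 0.0632 for VAV3, 0.0937 for KSR2, 0.102 for CBLN2, 0.0604 for HLF and 0.0552 for MNX1-AS1 over all alternatives. With normexp the log2 fold changes were closer to 0 than these bounds and folds: -0.91 for DOK7, -1.01 for GACAT2, -0.72 for CACNA1H, -0.54 for CHST9, -0.59 for KSR2, -0.59 for TMT1A, -0.40 for MNX1-AS1 and -0.42 for HLF. SLC47A2 and CBLN2 did not pass with normexp (-0.33 and -0.40), and ID2 and GACAT2 not without the filter on dim probes (limma adjusted p = 0.0511 and 0.0568).

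TGF-beta and SMAD target genes went both ways, with 2 of 20 measured up and 2 down (2 up and 5 down adjusted over the list alone; camera adjusted p = 0.146). INHBA, which encodes the activin A subunit, rose by 1.96 ± 0.24 and the collagen gene COL4A1 by 0.73 ± 0.11 on the log2 scale. The inhibitory SMAD gene SMAD6 had a log2 fold change of -1.60 ± 0.12 and ID2 -2.15 ± 0.24 (limma adjusted p from 0.00364 to 0.0157). Only 1 rose without control 1, control 2, control 3 or co-culture 1. Of 11 prostaglandin and arachidonate genes 1 rose and 3 fell (2 up and 4 down adjusted over the list alone; camera adjusted p = 0.224). ALOX5AP, the activating protein of 5-lipoxygenase, well above background on 1 of 3 control arrays, rose by 3.19 ± 0.66 on the log2 scale, and by 0.67 with normexp. The prostaglandin-degrading enzyme gene HPGD had a log2 fold change of -1.69 ± 0.18, ALOX5, the lipoxygenase itself, -0.70 ± 0.10 and the prostacyclin synthase gene PTGIS -0.95 ± 0.16 (limma adjusted p from 0.0076 to 0.041). With normexp HPGD had a log2 fold change of -0.51 and ABCC2 -0.68, and ALOX5 did not pass (-0.28, limma adjusted p = 0.129). ALOX5AP kept its call only without co-culture 2, and 1 gene fell without control 1, control 2, control 3 or co-culture 3. Of 19 oxidative stress and NRF2 target genes 2 fell, the drug transporter gene ABCC2 with -1.08 ± 0.16 and AKR1B10 with -2.03 ± 0.44, and 0 rose (1 up and 3 down adjusted over the list alone; camera adjusted p = 0.127). AKR1B10 did not pass with the trend and robust options (limma adjusted p = 0.0572). Without control 1, control 2, control 3 or co-culture 1 the falls numbered 0, and without co-culture 2 there was 1 fall and 1 rise. That list was called downward by camera with array weights (adjusted p = 0.0232), without control 1 (0.00655) and without co-culture 3 (0.0135).

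Transcripts of the stemness-associated list, named for a subject of the title, did not move together. The list fixed 21 genes, and SOX2, NANOG and PROM1 were among those not measured, that is, without a kept probe. Of 14 measured, 2 rose and 3 fell, with a median log2 fold change of 0.03 and a mean of -0.06 (3 up and 4 down adjusted over the list alone; camera adjusted p = 0.974, direction downward). The aldehyde dehydrogenase gene ALDH1A3 and the pluripotency factor gene POU5F1 rose by 0.68 ± 0.09 and 0.88 ± 0.12 on the log2 scale. With the mean over its 2 kept probes, 1 of which was called, ALDH1A3 had a log2 fold change of 0.26 and did not pass (limma adjusted p = 0.382). The surface marker gene CD24, the receptor kinase gene KIT and ALDH1A1 had log2 fold changes of -0.68 ± 0.09, -1.33 ± 0.18 and -1.38 ± 0.26 (limma adjusted p from 0.0129 to 0.0333). Without control 1 or control 2 0 of the 14 genes passed, and without co-culture 1 there was 1 rise and 1 fall. Mesenchymal genes were not called (2 of 19 measured up, LOX and ITGA5, and 0 down; 2 up and 2 down adjusted over the list alone; camera adjusted p = 0.403), and only 1 rose when any array other than co-culture 2 was left out. The collagen gene COL1A2 (log2 fold change -1.05, limma adjusted p = 0.0574) did not pass but passed downward with normexp (0.00643), probes well above background on all 6 arrays (0.0496), the trend and robust options (0.0302), array weights (0.028) and the replicate block (0.0212). COL5A1 passed downward with the last 3 of these (0.0211, 0.0366 and 0.0467). Epithelial genes were not called either, with 0 of 18 measured up and 1 down, the tight junction gene CLDN3 with a log2 fold change of -0.60 ± 0.10 (1 up and 2 down adjusted over the list alone). The mean over the epithelial genes was 0.08, the median -0.08 and the direction of camera downward (adjusted p = 0.668). In fits that left out 1 array CLDN3 kept its call only without co-culture 2, and 1 epithelial gene rose without control 1. With normexp CLDN3 had a log2 fold change of -0.37. The epithelial transcription factor gene ELF3 (log2 fold change 2.02, limma adjusted p = 0.0516) did not pass but passed upward with normexp (0.00226), median scaling (0.0364), probes well above background on all 6 arrays (0.0445), outlying spots left out (0.0495), array weights (0.0358) and the replicate block (0.0352). In the other direction, the keratin gene KRT7 (-0.39, limma adjusted p = 0.0703) passed downward with the trend and robust options (0.0169) and array weights (0.0441).

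Lists of general cell functions were not called. Amino acid starvation and ATF4 target genes had 1 of 20 measured up, CEBPB, and 1 down, CTH, the same numbers as adjusted over the list alone (camera adjusted p = 0.974). CEBPB kept its call only without co-culture 2, and the fall only without co-culture 2 or co-culture 3. Cholesterol synthesis (23 measured), heat shock (13), ribosomal protein (23) and mitochondrial respiratory chain genes (19) had 0 members past the limma threshold and 0 adjusted over the list alone (camera adjusted p = 0.766, 0.149, 0.403 and 0.768). The respiratory chain gene NDUFS1 (log2 fold change -0.35, limma adjusted p = 0.0523) passed downward with quantile normalization (0.0344) and array weights (0.0369). It also passed with the trend and robust options (0.00981) and with probes well above background on all 6 arrays (0.0478). The median log2 fold change of the ribosomal protein genes was 0.03 and over all genes 0.01. With normexp background correction the heat shock and ribosomal protein lists were called upward (camera adjusted p = 0.0203 and 0.0448). The heat shock genes HSPA1A and HSPA1B passed upward with normexp (limma adjusted p = 0.0122 and 0.0398), and HSPA1A also with the trend and robust options (0.0271).

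Markers of other cell types gave no list call. Myeloid and granulocyte markers, the type of cell added to the co-culture, were measured for 11 of 24 genes, of which 0 passed over all genes or adjusted over the list alone, with a median log2 fold change of 0.12 (camera adjusted p = 0.725). With the replicate block the lysosomal membrane protein gene LAPTM5 passed upward (log2 fold change 0.86, limma adjusted p = 0.0255, against 0.206 without the block). The calgranulin genes S100A8, S100A9 and S100A12 were not well above background on any array of either group. Among lymphocyte markers 1 of 8 measured rose, the interleukin 7 receptor gene IL7R, by 1.75 ± 0.21 on the log2 scale, and 0 fell, the same numbers as adjusted over the list alone. The median was -0.04, the mean 0.17 and the direction of camera upward (adjusted p = 0.768), and without control 1 the rises numbered 0. Fibroblast markers went both ways, with 2 of 7 measured up and 1 down (2 up and 2 down adjusted over the list alone). The median was -0.01, the mean -0.04 and the direction of camera upward (adjusted p = 0.959). The proteoglycan gene DCN was at least 2.64-fold higher and LUM rose by 0.93 ± 0.15 on the log2 scale. The growth factor receptor gene PDGFRB had a log2 fold change of -1.98 ± 0.15 (limma adjusted p = 0.0144, 0.0216 and 0.00364). With normexp DCN and LUM had log2 fold changes of 0.17 and 0.085 and did not pass (limma adjusted p = 0.469 and 0.714), and PDGFRB had -0.91. The rises numbered 0 without control 1 or control 2 and 1 without control 3, co-culture 1 or co-culture 3. Endothelial and erythroid markers, 7 measured each, had 0 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.768 for both).

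**Figure D3:**
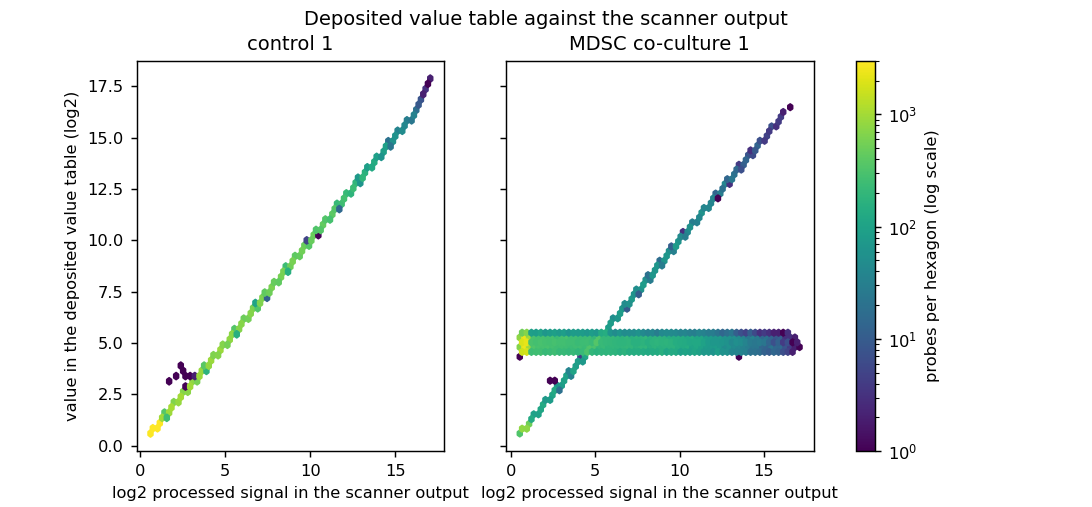
Values of the deposited value table (vertical axis, log2) against the log2 processed signal of the scanner output (horizontal axis) for all probes of control 1 (left) and co-culture 1 (right), coloured by the number of probes per hexagon on a log scale. The control values lie on the diagonal (r = 0.99997), while most co-culture values lie in a flat band and are unrelated to the array's signal (r = 0.342 over all rows).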

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

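The tests of the NF-kB rise, of the value table and of the splits for gene counts were chosen after their results had been seen.

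The deposited value table holds co-culture values that do not come from the arrays' signals. In 51083 of 58341 rows (87.6%) the 3 co-culture values lie on 1 straight line within 0.001 log2 units, against 7 rows of the control columns and 0 probes of the scanner output. In co-culture 1 these values span 4.49 to 5.46, have r = -0.00226 with the scanner output, and 100% of the steps between sorted neighbours equal the median step of 1.89e-05 within 1 percent, which is consistent with values filled in as an even series. The arrays' own signals are argued against by that r of -0.00226, and no biological explanation was tested. The 0 probes on that line decide little, because the line was fitted to the value table itself. Used as deposited the table would call 13625 of 15988 genes (85.2%) in limma, and the rows of CSF2 and of all but 3 of the 27 measured NF-kB list members do not follow the scanner output.

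Probes with no current gene symbol lie outside the gene results, and 317 of 6530 kept passed the limma threshold, 151 upward and 166 downward, of which 111 changed at least 2-fold. A probe on chromosome 4 from 74607982 to 74608041 (hg19), not well above background on any control array, was at least 21.6-fold higher (limma adjusted p = 0.0135). It ends 1224 bases before the CXCL8 probe, which also rose, so it need not report a separate transcript. A pair of probes on chromosome 12, from 127759994 to 127760053 and from 127758882 to 127758941, rose by 3.31 ± 0.33 and 3.17 ± 0.33 on the log2 scale (limma adjusted p = 0.00676 and 0.00721), and these 3 probes were chosen after their values were seen.

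The rise of 26 of 27 NF-kB and TNF target genes may come from the co-culture itself, as a response of SKOV3 cells. Scaling or background correction is argued against by at least 25 members passing under normexp, quantile and median scaling, with a list median of at least 2.07. RNA of the co-cultured myeloid cells in the SKOV3 RNA stays open: the largest log2 fold change of a measured myeloid marker, LAPTM5, was 0.863 ± 0.365 against the list's median of 2.96 with dim members at their bound, and LAPTM5 passed upward with the replicate block (limma adjusted p = 0.0255). S100A8, S100A9 and S100A12 were well above background on no co-culture array, but probes near background exclude nothing, and the criterion for this test was reset several times after values were seen.

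With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split, 1 of the 10, called 1138 genes and 345 genes at least 2-fold in limma, and the highest of the other splits called 0 and 0, with 132 to 737 genes at an unadjusted p under 0.05 against 4208. For lists, the real split called 17 with camera's preset correlation and the highest other split 14, or 12 among the splits that, like the real one, part all 3 same-numbered pairs, of which there are 4 in all. No other split had as many lists, so 1 of 10 did. Every other split mixes control and co-culture arrays in both groups, so a real difference would widen the spread within groups and lower the calls. The probes were also those kept by the real groups. The low gene counts of the other splits are therefore not separate evidence for the real one.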

How the results depend on the processing

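CSF2 was higher in co-culture under every alternative that gave a value, with a log2 fold change of 2.69 with normexp. Without the filter on dim probes limma called 116 genes and 106 at least 2-fold, with normexp 117 at least 2-fold, and with the trend and robust options 2045 genes; the cause was not tested. Rows of the value table that follow the scanner output gave 235 genes, 109 upward and 126 downward, 62 at least 2-fold and 4 lists, where only 2641 genes and 13 lists could be tested; the JAK-STAT3, glycolysis, p53 and housekeeping lists lost their call there. With the estimated correlation 0 lists were called in place of 17. Fry does not set a list against other genes. Its unadjusted p was 0.0511, 0.0838, 0.0915 and 0.108 for the immediate early, protease, metallothionein and unfolded protein lists. For every other list that camera called, fry gave an unadjusted p under 0.05. The same held for the heat shock, TGF-beta, prostaglandin and fibroblast marker lists, which camera did not call. Leaving out 1 array gave 218 to 943 genes, 160 to 365 at least 2-fold, 13 to 17 lists and CSF2 log2 fold changes of 6.71 to 7.67. CSF2 had no value where probes had to be well above background on all 6 arrays or in the usable rows of the value table. The fit with the replicate block called 1333 genes, 929 of them also called without it, 386 at least 2-fold and 17 lists, with CSF2 at 7.14 (limma adjusted p = 0.0196). It ended the calls of NUSAP1, CCNB2 and TFRC and added 11 of the reported genes that the rule names (FLT3LG, COL1A2, COL5A1, ELF3, PLAUR, MMP3, PLAU, GCLC, HMOX1, MT1X and LAPTM5), and changed no other call among these reported genes or the lists. A slide block was not run because all arrays share 1 slide.

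Sign changes, 36 over 14 genes and lists, all concerned values that passed in neither fit. With normexp the value was -0.014 for ITGB2 and the median was -0.016 for stemness, 0.044 for cholesterol synthesis, 0.069 for mitochondrial, -0.014 for myeloid marker, 0.050 for fibroblast marker and -0.021 for endothelial marker genes. With median scaling it was 0.012 for cholesterol synthesis, 0.0030 for mitochondrial and 0.0091 for fibroblast marker genes, and without the filter -0.024 for stemness and 0.055 for fibroblast marker genes. The mean over probes gave -0.0056 for RPL35, array weights 0.0088 for CD8A, -0.0041 for G1/S and -0.052 for ATF4 genes, and the value table -0.035 for ribosomal genes. Leaving out 1 array gave ranges of -0.023 to 0.11 for stemness, -0.11 to 0.14 for cholesterol synthesis, -0.077 to 0.019 for mitochondrial, -0.097 to 0.14 for ATF4, -0.0013 to 0.055 for G1/S, -0.00037 to 0.093 for ribosomal, -0.16 to 0.099 for fibroblast marker, -0.088 to 0.085 for lymphocyte marker and -0.18 to 0.0021 for erythroid marker genes, and -0.14 to 0.071 for CD8A. Signal over background limits fold changes of dim genes, which are given as bounds.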

Other observations

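Genes described in this part were chosen after their values were seen, apart from the tests of hypoxia and glycolysis genes for brightness and shared members, which were set beforehand.

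CD274, which encodes PD-L1, rose by 1.88 ± 0.31 on the log2 scale, and PDCD1LG2, which encodes PD-L2 and was not well above background in controls, was at least 1.43-fold higher (limma adjusted p = 0.0219 and 0.00201). The laminin subunit genes LAMA3 and LAMB3 rose by 2.44 ± 0.26 and 1.07 ± 0.15 on the log2 scale, and the matrix glycoprotein gene TNC by 2.18 ± 0.22 (limma adjusted p from 0.00702 to 0.0148). The EGF receptor ligand genes HBEGF and AREG rose by 1.61 ± 0.20 and 1.40 ± 0.23 (limma adjusted p = 0.0114 and 0.023), and the inflammasome sensor gene NLRP3 by 2.62 ± 0.33 (limma adjusted p = 0.0124).

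The hedgehog effector gene GLI1 had a log2 fold change of -1.61 ± 0.16, the bone morphogenetic protein gene BMP5 -1.64 ± 0.12 and the growth factor receptor gene FGFR2 -1.15 ± 0.13, and BMP4, well above background on 1 of 3 co-culture arrays, had -1.62 ± 0.27 (limma adjusted p from 0.00364 to 0.0218). The nuclear receptor genes NR3C2 and THRB had -1.27 ± 0.11 and -1.11 ± 0.14 (limma adjusted p = 0.00477 and 0.0113).

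Whether the falls of ID2 and SMAD6 belong to lower expression of BMP target genes as a group stays open. Of 10 other BMP target genes, 8 had log2 fold changes under 0, with a median of -0.165 (camera p = 0.0323 unadjusted, and p = 0.116 with an estimated correlation). The values of 4 of them had been seen before, and the 6 others went both ways, with 4 log2 fold changes under 0 and a median of -0.088 (camera p = 0.517 unadjusted, and p = 0.543 with an estimated correlation). None of the 10 passed the limma threshold.

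Hypoxia-induced and glycolysis genes together, 36 measured, had a median log2 fold change of 0.49, with 14 up and 0 down. A shift that depends on the brightness of the probes is argued against by the median's percentile of 100 among 10000 random lists matched on mean level, nearly all of which had medians between -0.04 and 0.10. Without the members shared with the NF-kB, JAK-STAT3, mesenchymal or interleukin lists the 34 others had a median of 0.471, with 12 up and 0 down. Their camera p was 3.15e-13 unadjusted, and 0.0044 with an estimated correlation. These values argue against the few shared members as the source of the rise. More cells in the co-culture wells than in the control wells could also raise such genes and cannot be told apart from an effect of MDSCs, because the design holds 0 wells with other added cells.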
